A study of Homo sapiens with 8 samples.

How the data were processed

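Total RNA of HEK293 cells was compared on 8 Agilent 2-colour arrays, each with 45015 spots, of which 1639 were controls. Per the labels, the RNAs labelled siWRN were in Cy3 on 4 arrays and in Cy5 on 4, against a scrambled RNA in the other dye. Arrays were grouped by the siRNA and the replicate number in the labels. Per the file headers, Feature Extraction 10.5.1.1 measured the intensity of each spot and of its local background as medians of pixels, and deposited per-spot flags and other indicators. Per the file headers, the same software made processed intensity values, background-subtracted, spatially detrended and dye-normalized, and from them a log10 ratio of red over green. The authors' series matrix holds log2 ratios of the same arrays, for which the submitters' processing notes name limma, with no version. Its column medians lay between -0.00 and 0.01. Against the scanner's red-over-green ratios the slopes were 0.79 to 0.93 and the correlations 0.60 to 0.83 across probes, so its sign follows red over green on every array and was turned here for the dye swap. The authors' exact background and normalization steps are not given in the sources used here.

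The median spot signals and median local backgrounds were corrected with normexp (offset 50) in limma 3.58.1 on R 4.3.3, in place of the mean spot signals planned before the data were examined, and normalized by loess within each array with weight 0 for control spots and outlier-flagged spots. Between 100.0 and 182 spots per array were flagged as outliers and left out. Each log2 ratio was turned to labelled siWRN over labelled scrambled. Spots of a probe were averaged: 264 of the 41000 probes were present 10 times. Probes were kept where well above background in at least 0.75 of the array channels of the scrambled, siWRN385 or siWRN387 RNAs, which left 38246, and a gene was tested only with a value on all arrays. Probe accessions were matched, without versions, to a RefSeq gene table of assembly GRCh38.p14. It named 25398 probes with 17240 symbols. Other probes kept the file's accession, and no coordinates are given because the array design used another genome build. The brightest probe by mean intensity over the arrays stood for a gene, which gave 29805 genes, 16624 of them with a symbol. Among the genes named, 30 had other kept probes, and 6 of these 39 probes had the opposite sign to a ratio larger than the square root of 1.5-fold; those of BAX, KCNC1 and SMOC1 are given with the results, as are some others that read far weaker. The others belonged to DGCR8 (0.02 and -0.03) and MRE11 (0.05 and -0.02). No named gene was saturated, and all named were well above background on every array.

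The dye-swapped arrays of a pair were averaged to 4 ratios, fitted together in limma with lmFit and eBayes (2 residual and 14.9 prior degrees of freedom), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every SE given is limma's moderated one. It draws on the ratios of both siRNAs and, through the prior, on all genes, so it is not the spread of the 2 ratios of one siRNA. The labels call the replicates biological and say nothing further of separate cultures, so p-values measure the spread between these RNAs. The scrambled RNA of a replicate number was taken as the same RNA with both siRNAs, which the labels do not state outright. For the average of both siRNAs the replicate number was a random block. limma's duplicateCorrelation gave no value with 4 ratios, so the correlation was taken from the differences between replicate numbers within each siRNA (0.08). Gene lists, written before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg over all 36 lists, and also with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. In the average, those 2 tests ran without the block. The genes named follow a rule written before the data were examined. WRN and the other RecQ helicases are always named. For each siRNA and the average, the rule takes the 10 highest and 10 lowest ratios among genes past the threshold with a gene symbol and the same sign on every array. For the difference it takes the 5 highest and 5 lowest, with the same sign in the differences of both replicate numbers. From each list it takes up to 4 members of smallest p in the average and up to 4 more that passed in a comparison; the text names some of these genes and leaves others out. The smooth trend over spot position was measured with mgcv 1.9.3.

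Position on the slide accounted for 52.4% to 66.2% of the variance of the ratios on single siWRN385 arrays, 11.0% to 33.7% on siWRN387 arrays, and 2.85% to 19.2% of the dye-averaged ratios. In the processed signals it accounted for 1.92% to 7.12% on single arrays. Opposite dye orientations of the same RNAs correlated at -0.66 to -0.14 across genes after turning, so dye and position terms outweighed the siRNA effect on single arrays and the averages rest on the swap. The tests were tested on simulated data: ratios of 8 arrays with the real spreads and gene-specific dye terms, shared scrambled RNAs, 29805 genes and known changes. In the simulated siWRN385 comparison, 98.0% of genes changed 1.25-fold and 100.0% of genes changed 1.5-fold were recovered. In the simulated difference, 73.0% of genes changed 1.25-fold were recovered. Of the genes called, 1.73% were unchanged for siWRN385, 2.46% for siWRN387 and 6.27% for the average. The simulated dye term was the same on every array, so it cancelled in the swap average. No position trend and no separate noise of single arrays were put in. The shares therefore do not tell how many of the real calls come from dye or position terms left after averaging.

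The alternatives were processed signals, no background subtraction, median centring, Aquantile scaling, other filters and probe rules, an 8-array fit with a dye term, each dye orientation alone, eBayes with trend and robust settings, each ratio left out, the series matrix, the replicate number as a fixed block, and other thresholds. Removal of the position trend was added after the data had been examined. Slide could not be fitted as a block, since each slide held 1 siRNA. A planned search for siRNA seed sites in 3′ UTRs was not run, because no transcript sequences were used here.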

Results

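Gene expression was measured in HEK293 cells, a human embryonic kidney line that carries adenovirus E1 genes, 72 h after transfection with an siRNA against WRN or with a scrambled siRNA. WRN encodes the RecQ DNA helicase and exonuclease that is mutated in Werner syndrome. The labels name 2 siRNAs of 25 nt: siWRN385, given as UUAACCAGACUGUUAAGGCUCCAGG, and siWRN387, given as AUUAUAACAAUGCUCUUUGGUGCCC. Each of 8 Agilent 2-colour arrays carried one siWRN RNA against one scrambled RNA, and each of the 4 RNA pairs (2 biological replicates per siRNA) was hybridised in both dye orientations. The dye swap of a pair was averaged, which left n = 2 ratios per siRNA, and the number of arrays limits the precision. The scrambled RNAs carry the same replicate numbers with both siRNAs and were taken as the same RNAs, which the labels do not state outright. The median spot signal lay between 290.0 and 698 brightness units per channel, over a local background of 33.0 to 41.0, and 83.6% to 95.9% of spots were well above background. All siWRN385 arrays lay on slide 1 and all siWRN387 arrays on slide 2, so slide and siRNA cannot be told apart in comparisons between siRNAs.

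The targeted gene was examined first, because it checks the labels. On all 8 arrays the normalized WRN ratio of labelled siWRN over labelled scrambled was above 0, which goes against a knockdown. The log2 ratio was 0.78 ± 0.05 (moderated SE, n = 2) for siWRN385 and 0.71 ± 0.05 (moderated SE, n = 2) for siWRN387, or 1.72-fold and 1.63-fold, with limma adjusted p of 4.81e-08 and 6.62e-08. The 2 dye-averaged ratios were 0.82 and 0.75 for siWRN385, and 0.64 and 0.78 for siWRN387. Single arrays ranged from 0.50 to 0.99. The ratio differed between the siRNAs by -0.08 ± 0.07 (limma adjusted p = 0.607). For this reason the RNAs are called "labelled siWRN385" or "labelled siWRN387" throughout, every direction is that of the labels, and exchanging the dyes on all arrays would turn each sign. A gene higher in the labelled siWRN RNA lay on the same side as WRN, whichever way the labels are read. Among the other RecQ helicases, BLM (-0.02 and 0.03), RECQL (0.05 and 0.16) and RECQL5 (-0.01 and 0.13) did not pass with siWRN385 or siWRN387. RECQL4 was -0.15 ± 0.05 with siWRN385 (limma adjusted p = 0.0481), with a ratio below 0 on only 2 of the 4 arrays, and did not pass from the scanner software's processed signals (adjusted p = 0.149) or with any of the 4 ratios left out (adjusted p from 0.0593 to 0.366).

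**Figure D1:**
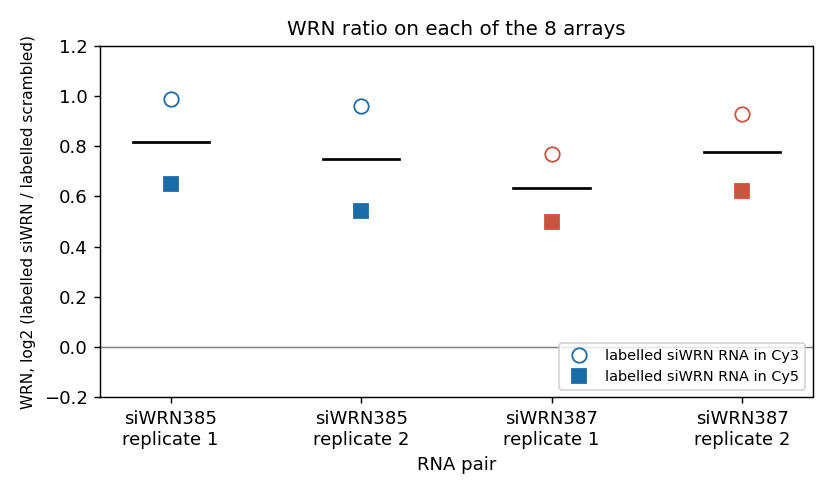
WRN log2 ratio of the RNA labelled siWRN over the RNA labelled scrambled on each of the 8 arrays, by RNA pair; open circles have the labelled siWRN RNA in Cy3, filled squares in Cy5, and bars are the mean of the 2 arrays of a pair. All 8 points lie above 0, between 0.50 and 0.99.

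Among genes with the same sign on every array, CTSZ, a lysosomal cysteine protease, at 1.5 ± 0.06, LAMP1, a lysosomal membrane glycoprotein, at 1.49 ± 0.06, and TBCA, a tubulin-folding cofactor, at 1.24 ± 0.05, lay far on WRN's side with siWRN385 (log2 ratio ± SE, n = 2). TAF15, an RNA-binding protein of the FET family, stood at 1.17 ± 0.07, with NRP1 (0.96), SMOC1 (0.95), TRIAP1 (0.92), the zinc transporter SLC39A7 (0.91) and PSMD10 (0.90) also high. All were higher on 4 of 4 arrays, although dimmer probes read -0.25 for SMOC1, 0.49 for LAMP1, and 0.09 and 0.72 for NRP1. Far on the other side were INHBB, the activin beta-B subunit, at -0.88 ± 0.05, the mitochondrial import subunit TIMM17B at -0.81 ± 0.05, INSIG1, which restrains sterol synthesis, at -0.76 ± 0.06, and TLE5 at -0.75 ± 0.05, with dimmer probes at -0.45 and -0.26. IGF2 (-0.62, with a dimmer probe at -0.09 and no call on the Cy3 arrays alone), the oxygen sensor EGLN1 (-0.62, with a dimmer probe at -0.31), KCNC1 (-0.58, with 2 dimmer probes at -0.02 and 0.07), GPER1 (-0.56), CAP1 (-0.56) and the isoprenoid enzyme IDI1 (-0.55) were lower on 4 of 4 arrays. limma adjusted p was 4.44e-06 or smaller for each of these genes. Of 29805 genes tested, 4806 passed an adjusted p under 0.05 in limma, 2789 higher and 2017 lower in the labelled siWRN385 RNA, and 79 of them differed by at least 1.5-fold, 69 higher and 10 lower. From processed signals 3151 genes passed, 197 of them at least 1.5-fold (173 higher and 24 lower), and with median centring in place of loess 3683 of 4830 were higher.

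With siWRN387, the cystine transporter SLC7A11 stood at 1.75 ± 0.06, asparagine synthetase ASNS at 1.60 ± 0.08, cystathionine gamma-lyase CTH at 1.56 ± 0.05, and ATF4, the transcription factor of the amino acid response, at 1.21 ± 0.05 (log2 ratio ± SE, n = 2). The cationic amino acid transporter SLC7A1 (1.1, with a dimmer probe at 0.20), PCK2 (1.14) and the secreted glycoprotein STC2 (1.15) were also among the 10 highest, with TAF15 (1.52), CTSZ (1.16) and the ubiquitin-conjugating enzyme UBE2E1 (1.14). The lowest were INHBB at -0.98 ± 0.05 and HSPA8, the constitutive HSP70 chaperone, at -0.85 ± 0.05. KCNC1 (-0.82, with dimmer probes at 0.06 and -0.02), CAP1 (-0.77), ZFP36L2 (-0.76), PRDM16 (-0.76), TIMM17B (-0.74), SFT2D3 (-0.68), COL18A1 (-0.66) and TLE5 (-0.62) completed the set, although dimmer probes read -0.16 for SFT2D3, -0.10 for COL18A1, and -0.33 and -0.24 for TLE5. Each of the 20 had the same sign on 4 of 4 arrays and a limma adjusted p of 2.05e-07 or smaller. In all, 5544 genes passed, 2691 higher and 2853 lower in the labelled siWRN387 RNA. At least 1.5-fold were 158, 130 higher and 28 lower, or 251 from processed signals. The count fell to 3552 without siWRN387 replicate 1 and to 2584 without replicate 2, where the remaining ratio is assumed to vary like those of the other siRNA.

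Genes that passed with both siRNAs and in the same direction numbered 1650, 887 higher and 763 lower in the labelled siWRN RNA. Independent lists of these sizes would share 252 higher and 193 lower genes, 445 in all, and 306 genes passed with opposite signs, against 449 expected. In 20 simulations of unchanged groups that share the scrambled RNAs of a number, 0 genes were called with both. The independent value leaves out the shared controls, and the simulated one leaves out any change. Among genes with the same sign on all 8 arrays, the average of both siRNAs was high for TAF15 (1.35 ± 0.05), CTSZ (1.33 ± 0.04), SLC7A11 (1.05 ± 0.04), SLC39A7 (0.95 ± 0.04) and SMOC1 (0.95 ± 0.05), and also for the stress cytokine GDF15 (0.88 ± 0.04), TMED9 (0.80 ± 0.06), neurofilament NEFM (0.75 ± 0.04) and WRN (0.75 ± 0.04). It was low for INHBB (-0.93 ± 0.04), TIMM17B (-0.78 ± 0.04), KCNC1 (-0.70 ± 0.04), TLE5 (-0.69 ± 0.04), CAP1 (-0.67 ± 0.04), ZFP36L2 (-0.57 ± 0.04), IGF2 (-0.51 ± 0.04), PIP4K2A (-0.50 ± 0.04), GPER1 (-0.50 ± 0.04) and IGFBP5 (-0.49 ± 0.04). Dimmer probes read -0.14 with siWRN385 and -0.18 with siWRN387 for PIP4K2A, and -0.09 and -0.37, and -0.04 and -0.14, for IGFBP5. The dimmer probe of SMOC1 read -0.25 and -0.41, opposite in sign to its average. For all of these genes limma gave an adjusted p of 1.66e-07 or smaller. Nuclear lamin LMNB1 was on WRN's side with both siRNAs, at 0.60 and 0.75. The average called 6465 genes, 3523 higher and 2942 lower, and with median centring 3152 of 4918 were higher.

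Across genes, which are not independent replicates, the mean ratios of the siRNAs correlated at r = 0.36 (Spearman rho 0.27), where simulated unchanged groups gave r = 0.50 if the scrambled RNA of a number is shared. Their covariance was 0.00648, against 0.00136 simulated. Both simulated values follow from the setting, which gave the shared scrambled RNA the same variance as the siWRN RNA. In the data, deviations of ratios with the same number correlated at only 0.08, so the simulated values are no measure of what sharing gives here. Ratios of different replicate numbers, which share no scrambled RNA if a number marks one RNA, correlated at 0.22 and 0.36, and those of the same number at 0.24 and 0.39. Replicates of one siRNA correlated at 0.66 for siWRN385 and 0.74 for siWRN387. They also shared a slide, which ratios of different siRNAs did not, so a part of the slide in these higher values cannot be told apart. From processed signals, 1006 genes passed with both siRNAs in the same direction, and without siWRN387 replicate 2, 829 did.

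**Figure D2:**
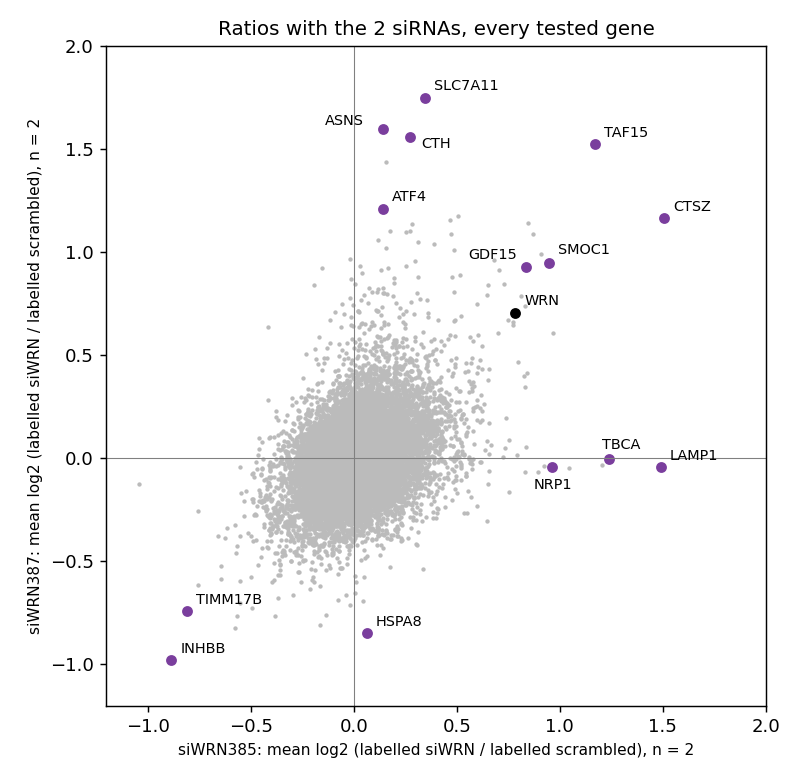
Mean log2 ratio (labelled siWRN over labelled scrambled, n = 2) of every tested gene with siWRN385 (x axis) and siWRN387 (y axis); named genes are marked in purple and WRN in black. WRN (0.78 and 0.71), CTSZ and TAF15 lie far from 0 on both axes, LAMP1, TBCA and NRP1 along the siWRN385 axis, and SLC7A11, ASNS, CTH and ATF4 mainly along the siWRN387 axis.

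The difference between the siRNAs (siWRN387 minus siWRN385) was tested directly. ASNS (1.46 ± 0.11), SLC7A11 (1.40 ± 0.08), CTH (1.28 ± 0.07), ATF4 (1.07 ± 0.07) and ELSPBP1 (1.05 ± 0.08) were the 5 highest (log2 difference ± SE). LAMP1 (-1.53 ± 0.09), TBCA (-1.25 ± 0.07), NRP1 (-1.0 ± 0.08) and PSMD10 (-0.96 ± 0.07) were among the lowest. LAMP1, TBCA, NRP1 and PSMD10 had ratios between -0.07 and -0.01 with siWRN387, and none of these 4 passed there. Dimmer probes differed less, at 0.49 with siWRN385 and 0.07 with siWRN387 for LAMP1, and 0.09 and 0.01, and 0.72 and 0.27, for NRP1. HSPA8 read 0.06 with siWRN385 (adjusted p = 0.477) and differed by -0.91 ± 0.07. ELSPBP1 was lower with siWRN385 (-0.42) and higher with siWRN387 (0.63). In total 3119 genes differed, 1297 higher and 1822 lower with siWRN387. From processed signals 988 differed, without siWRN387 replicate 1 1960 did, and with median centring 625 of 3144 were higher.

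Of 36 gene lists, camera with a preset correlation called 9 with siWRN385, 8 with siWRN387 and 11 in the average. With an estimated inter-gene correlation, from 2 residual degrees of freedom, none of these calls held: the smallest adjusted p was 0.486, 0.467 and 0.395. With so few degrees of freedom that test could hardly pass over 36 lists, so its failures do not show that correlation between genes made the calls. For the p53 target genes with siWRN385 the estimated correlation was -0.02, below the preset one. Their unadjusted camera p still went from 3.20e-14 to 0.0135. Estimates for other called lists lay on both sides of the preset one, from -0.05 for heat shock genes to 0.21 for extracellular matrix genes. They were 0.15 for the amino acid response, 0.15 for NF-kB, 0.14 for glycolysis and 0.17 for hypoxia-inducible genes. For lists with such estimates the preset correlation may be too low and the camera p too small. The amino acid response genes had all 21 measured members higher in the labelled siWRN387 RNA (21 also when adjusted over the list alone), with a median of 0.73 and a camera adjusted p of 5.28e-41 (adjusted p = 0.467 with an estimated correlation). With siWRN385, 9 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 5.76e-06 (0.535 estimated). Serine synthesis enzyme PSAT1 (0.25 with siWRN385, 1.09 with siWRN387), stress regulator NUPR1 (0.30 and 0.96) and CEBPB (0.20 and 0.87, but -0.12 and 0.06 at a dimmer probe) were among them. The p53 target genes showed 16 of 27 higher and 0 lower with siWRN385 (19 adjusted over the list alone), with a camera adjusted p of 1.15e-12 (adjusted p = 0.486 with an estimated correlation). With siWRN387, 9 were higher and 0 lower (10 over the list alone), with a camera adjusted p of 0.00181 (0.467 estimated). The median of the p53 list was 0.26 with siWRN385 and 0.06 with siWRN387. It depended on the dye. On siWRN385 arrays it was 0.39 and 0.45 with the labelled siWRN RNA in Cy3, but 0.07 and 0.10 in Cy5. On siWRN387 arrays it was 0.20 and 0.22 in Cy3, but 0.03 and 0.06 in Cy5. GDF15 (0.84 and 0.93), FDXR (0.42 and 0.29), FAS (0.44 and 0.28) and GADD45A (0.45 and 0.25) were higher with both, DDB2 (0.43 and 0.05) with siWRN385, and SESN2 (0.17 and 0.65) with siWRN387. SESN2 is also on the amino acid response list. BAX read 0.49 and 0.66, but its dimmer probe -0.17 and 0.12. With siWRN385, FDXR did not pass on the Cy3 arrays alone (0.14, adjusted p = 0.255), nor FAS (0.15, adjusted p = 0.264) and BAX (0.23, adjusted p = 0.0759) on the Cy5 arrays alone. Of the unfolded protein response genes, 14 of 20 were higher with siWRN385 (17 over the list alone, camera adjusted p = 1.00e-11, adjusted p = 0.505 with an estimated correlation). With siWRN387, 5 were higher and 3 lower (5 and 3 over the list alone), and the list was not called (camera adjusted p = 0.581). SYVN1 (0.38 with siWRN385, 0.05 with siWRN387) and DNAJB9 (0.35 and 0.07) passed with siWRN385 alone. SYVN1, with a dimmer probe at 0.14, did not pass there from processed signals (adjusted p = 0.0540) or on the Cy5 arrays alone (0.0797), nor DNAJB9 on the Cy3 arrays alone (0.221). XBP1 (0.41 and 0.67) and HERPUD1 (0.31 and 0.80) passed with both and read higher with siWRN387, where only HERPUD1 passed the test of the difference. With siWRN385, XBP1 and HERPUD1 averaged below 0, at -0.10 and -0.08, over the arrays with the labelled siWRN385 RNA in Cy5.

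Cholesterol biosynthesis genes lay opposite to WRN with both siRNAs. With siWRN385, 14 of 23 were lower and 3 higher (15 and 3 adjusted over the list alone, camera adjusted p = 2.58e-05, adjusted p = 0.535 with an estimated correlation). With siWRN387, 16 were lower and 0 higher (16 over the list alone, camera adjusted p = 1.73e-09, adjusted p = 0.467 with an estimated correlation). IDI1 (-0.55 and -0.38), squalene synthase FDFT1 (-0.40 and -0.28), SQLE (-0.24 and -0.42) and HMGCS1 (-0.16 and -0.48) passed with both siRNAs. Glycolysis genes were lower with siWRN385 in 14 of 20 (15 over the list alone, camera adjusted p = 1.13e-08, adjusted p = 0.535 with an estimated correlation), such as PGAM1 (-0.40) and hexokinase HK2 (-0.45, with a dimmer probe at -0.02). With siWRN387, 4 were lower and 2 higher, and the list was not called (camera adjusted p = 0.489), but PGAM1 (-0.37) passed. Hypoxia-inducible genes were lower with siWRN385 in 9 of 19 and higher in 2 (9 and 2 over the list alone, camera adjusted p = 0.000889, adjusted p = 0.573 with an estimated correlation), with EGLN1, MXI1 (-0.40) and BNIP3 (-0.39) among the lower. With siWRN387, 6 were lower and 3 higher, and the list was not called (camera adjusted p = 0.544), but EGLN1 (-0.34), MXI1 (-0.31) and BNIP3 (-0.24) passed. MYC and its targets were lower with siWRN385 in 7 of 20 (9 over the list alone, camera adjusted p = 0.000393, adjusted p = 0.535 with an estimated correlation), as was the transferrin receptor TFRC (-0.34). With siWRN387, 7 were also lower and 2 higher, TFRC (-0.31) among the lower, and the list was not called (camera adjusted p = 0.365). With siWRN385, TFRC (-0.09, adjusted p = 0.474) and MXI1 (-0.20, adjusted p = 0.0864) did not pass on the Cy3 arrays alone, nor BNIP3 (-0.19, adjusted p = 0.135) on the Cy5 arrays alone. NF-kB and inflammatory genes were higher with siWRN387 in 11 of 20 (11 over the list alone, camera adjusted p = 1.51e-06, adjusted p = 0.508 with an estimated correlation) and with siWRN385 in 5 (6 over the list alone, camera adjusted p = 0.0163, adjusted p = 0.635 with an estimated correlation). The siWRN385 call did not hold without siWRN385 replicate 2 (adjusted p = 0.104) or with median centring (0.0528). RELB (0.47 and 0.48), NFKBIA (0.31 and 0.33) and BIRC3 (0.20 and 0.56) were higher with both. Autophagy and lysosome genes, 7 of 23 higher and 4 lower with siWRN385 (8 and 4 over the list alone), were called (camera adjusted p = 0.0313, adjusted p = 0.573 with an estimated correlation), but not from processed signals (0.174), without siWRN385 replicate 1 (0.190) or with the position trend removed (0.0663). On siWRN385 arrays the median of this list was 0.19 and 0.16 with the labelled siWRN RNA in Cy3, but -0.13 and -0.15 in Cy5. With siWRN387, 3 of these genes were higher and 3 lower, without a call (camera adjusted p = 0.544).

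**Figure D3:**
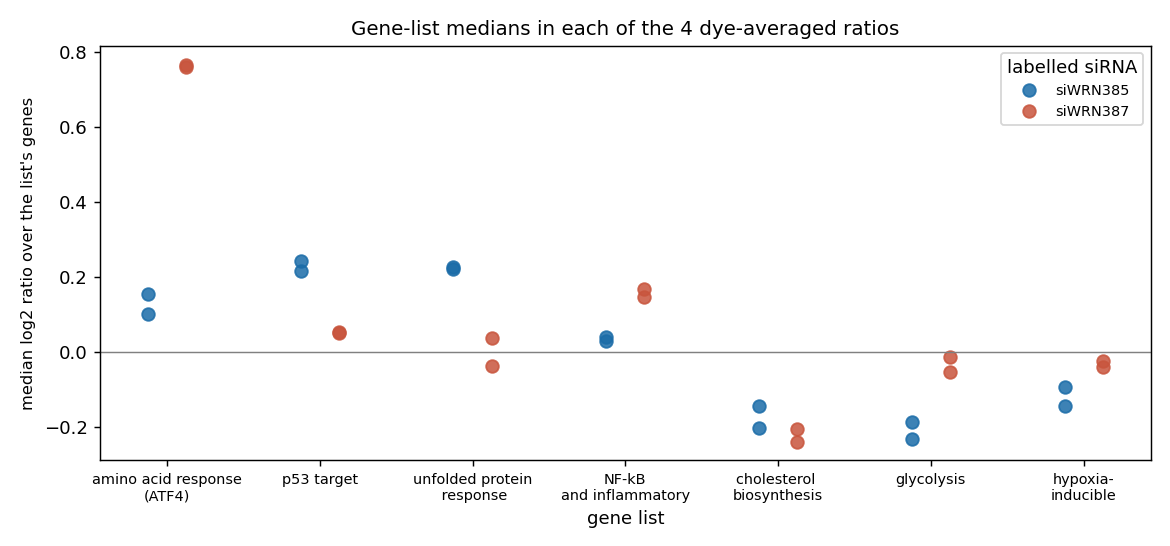
Median log2 ratio (labelled siWRN over labelled scrambled) over the measured genes of 7 gene lists in each of the 4 dye-averaged ratios, 2 points per siRNA. The amino acid response list stands highest with siWRN387, and the cholesterol biosynthesis medians are below 0 in all 4 ratios.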

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

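The tests of explanations in this part were chosen after the results were seen; the test of the difference between the siRNAs was planned. Directions are those of the labels, which the WRN ratio goes against, and exchanging the dyes would turn every sign.

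The siRNAs differed at 3119 genes (limma, siWRN387 minus siWRN385). Higher with siWRN387 were ASNS (1.46), SLC7A11 (1.40), CTH (1.28), ATF4 (1.07), ELSPBP1 (1.05), SLC7A1 (0.92), PCK2 (0.85), PSAT1 (0.84), STC2 (0.69), CEBPB (0.68), NUPR1 (0.66), GINS4 (0.63), NEFM (0.52), HK2 (0.52), MCM4 (0.52), EGR1 (0.50), INSIG1 (0.50), HERPUD1 (0.49), SESN2 (0.49), VEGFA (0.44), BIRC3 (0.36), TAF15 (0.35), EGLN1 (0.28), CLSPN (0.24) and IGF2 (0.24). Lower with siWRN387 were LAMP1 (-1.53), TBCA (-1.25), NRP1 (-1.0), PSMD10 (-0.96), TRIAP1 (-0.96), HSPA8 (-0.91), NDUFB3 (-0.72), PRDM16 (-0.63), OCLN (-0.54), CDH1 (-0.45), HMOX1 (-0.44), ZFP36L2 (-0.38), COL6A1 (-0.38), DDB2 (-0.38), COL18A1 (-0.37), CTSZ (-0.34), SYVN1 (-0.33), HMGCS1 (-0.33), SFT2D3 (-0.31) and DNAJB9 (-0.28). On the Cy3 arrays alone the difference did not pass for SLC7A1 (0.28), MCM4 (0.0591), EGR1 (0.0912) and CDH1 (-0.21), nor from processed signals for HK2 (adjusted p = 0.0603) and CDH1 (0.0520). Dimmer probes (siWRN385, then siWRN387) lay closer together for COL6A1 (-0.05, -0.11), SFT2D3 (-0.12, -0.16) and HMGCS1 (-0.31, -0.39). So did those of HK2 (-0.02, 0.07), SLC7A1 (0.01, 0.20), CEBPB (-0.12, 0.06) and IGF2 (-0.09, -0.02), and those of LAMP1 and NRP1 given above. The dimmer COL18A1 probe (-0.15, -0.10) differed in the opposite direction. Dimmer probes of HSPA8, SLC7A11, OCLN and GINS4 differed much as the brightest did. Among lists, camera called a difference for the amino acid response (median 0.66), glycolysis (0.15), hypoxia-inducible (0.0768) and NF-kB genes (0.0541) on the higher side. On the lower side it called the unfolded protein response (-0.23), p53 target (-0.12) and extracellular matrix genes (-0.11). With an estimated correlation the adjusted p of each of these 7 was 0.587. Under fry 0 of the 36 lists passed for the difference, and the adjusted p of the amino acid response genes was 0.110.

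The WRN ratio, normalized and in the direction of the labels, was above 0 on all 8 arrays. Dye bias of the probe is argued against, since it would give opposite signs in the 2 orientations and the lowest ratio was 0.50. A candidate explanation is that the dye labels are exchanged on all arrays, which would make the WRN ratio a knockdown. Of the changes of at least 1.5-fold found with one siRNA and not the other, where lowered off-target mRNAs would then lie, 87.5% (35 of 40) with siWRN385 and 85.3% (99 of 116) with siWRN387 were on WRN's side, against 87.2% (34 of 39) and 73.8% (31 of 42) of the other changes of that size (Fisher's exact p = 1 and 0.103). Fisher's test takes genes as independent, which genes that move together are not, so its p-values only describe the shares. Exchanged labels cannot be told apart from an uneven response of the cells by these shares, and a true increase of WRN mRNA was not tested.

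Changes shared by both siRNAs could come from chance values of a scrambled RNA shared within a replicate number. If a number marks the same scrambled RNA with both siRNAs, which the labels do not state outright, the covariance between different numbers is free of such values, and at 0.92 of that within a number it argues against them as the main cause. If it does not, no such values were shared within a number, and the comparison tests nothing. A lasting effect of the scrambled siRNA itself cannot be told apart from an effect of the WRN siRNAs: the shared calls were 3.71 times the independent expectation, and both readings allow that. Untransfected cells were not analysed here.

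The amino acid response genes stood apart with siWRN387. Dye or position bias is argued against by their median relative to that of all genes, which was at least 0.70 on each of the 4 siWRN387 arrays from both the main and the processed signals. A larger WRN change with siWRN387 is argued against, since the 95% upper bound of the WRN difference was 0.0768. A general unfolded protein response is argued against, since the median of those genes was lower with siWRN387 by -0.23 (9 of 20 lower, with HERPUD1, at 0.49, the 1 higher; from processed signals by -0.22, with only 2 lower and 1 higher), and from both signals 0.11 or less on each siWRN387 array against 0.15 or more on each siWRN385 array. An action of siWRN387 on a gene other than WRN, and the transfections or slide of that siRNA, stay open and were not tested. ATF4 was higher in the labelled siWRN387 RNA (1.21), so a lowering of its own mRNA by the siRNA is a possible point of entry only if the labels are exchanged.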

How the results depend on the processing

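The alternatives were fixed before the data were examined, except removal of the position trend, and no cause was tested unless stated. Both WRN ratios kept their sign and passed under every alternative run (0.60 to 0.97 for siWRN385, 0.56 to 0.85 for siWRN387); each ratio left out gave 0.75 to 0.82 and 0.64 to 0.78. Aquantile moves only mean brightness and so left ratios as they were. Processed signals called 3151 genes for siWRN385, 988 for the difference and 1006 with both siRNAs. Only arrays with the labelled siWRN RNA in Cy5 called 11636 for siWRN385 and 5974 for the difference; only those in Cy3 called 14323 for siWRN385, 11771 for the average and 3316 with both, and gave a correlation of 0.54. One orientation keeps the dye term by construction. At 1.5-fold or more the counts were 79 and 158 for the siRNAs, 61 for the average, 153 for the difference and 26 with both, and from processed signals 197, 251, 114 and 256 for the first 4. Left-out ratios gave 3249 to 4991 genes for siWRN385, 2584 to 6599 for siWRN387, 4393 to 6343 for the average, 1960 to 2858 for the difference and 829 to 1399 with both; a siRNA with 1 ratio left was assumed to vary like the other. Removing the position trend did not lower the counts (5258, 6489, 7081, 3477 and 1978).

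The lists called numbered 15 for siWRN385 with median centring, 4 with fry, and 0 for siWRN385, 0 for siWRN387 and 0 for the average with camera's estimated correlation, against 9, 8 and 11. Of the siWRN385 calls, fry kept the p53 target and unfolded protein response genes, and added double-strand break repair genes and apoptosis regulators. It did not keep MYC (fry adjusted p = 0.0983), cholesterol and glycolysis (0.101 each), or amino acid response, hypoxia-inducible, NF-kB and autophagy genes (0.108 each). With siWRN387 fry called 9 lists, but not the histone (fry adjusted p = 0.0623) or extracellular matrix genes (0.191). At an unadjusted p under 0.05 the estimated correlation called 2 lists for siWRN385, 2 for siWRN387 and 3 for the average. Left-out ratios gave 9 to 10, 7 to 12 and 10 to 16 lists. As a replicate block, the shared number gave 5796 genes for siWRN385, 6438 for siWRN387, 4134 for the difference and 2094 with both, with no replicate block 6854 for the average; the deviations of ratios with the same number correlated at 0.08, which does not settle whether a number marks the same scrambled RNA. With siWRN385, XBP1 (-0.10) and HERPUD1 (-0.0773) fell below 0 and RECQL4 (0.0626) rose above it on Cy5 arrays alone. These 3 lost their call, as did 31 other values of named genes under an alternative, and 2288 did not. Of list values with the preset correlation 16 lost their call and 208 did not. The list values came from median centring, processed signals, a changed replicate block, left-out ratios and removal of the position trend. Lists were not tested on each dye orientation alone. With no filter on dim probes 4726 genes were called for siWRN385, and 4673 with both channels well above background on all arrays.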

Other observations

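Several groups fell outside the comparisons above; directions are those of the labels, which the WRN ratio goes against. In the labelled siWRN387 RNA, replication genes GINS4 (0.80), a subunit of the replicative helicase, and MCM4 (0.54) were higher, but of 30 G1/S and replication genes 6 were higher and 1 lower, and the list was not called (camera adjusted p = 0.0907). Of 30 double-strand break repair and fork protection genes, 10 were higher and 2 lower with siWRN387 (camera adjusted p = 0.0131, adjusted p = 0.467 with an estimated correlation). CLSPN (0.39) and MRE11 (0.37, with a dimmer probe at -0.02) were higher, but both lost their call on the arrays with the labelled siWRN387 RNA in Cy5. The median of the list was 0.19 and 0.20 on the arrays with that RNA in Cy3, but -0.04 and 0.02 in Cy5. The list call did not hold without siWRN387 replicate 1 (adjusted p = 0.101) or with median centring (0.0537), and with siWRN385 7 were higher and 1 lower, without a call (0.0631). Replication-dependent histone genes were higher in 7 of 25 and lower in 1 (camera adjusted p = 0.00578, adjusted p = 0.467 with an estimated correlation), as for H1-2 (0.32), which did not pass on the Cy5 arrays alone (0.10). Heat shock genes were lower in 7 of 17 and higher in 1 (camera adjusted p = 0.0104, adjusted p = 0.467 with an estimated correlation), led by HSPA8 (-0.85) and DNAJB1 (-0.35), which did not pass on the Cy5 arrays alone (-0.21). Extracellular matrix genes were lower in 7 of 26 and higher in 1 (camera adjusted p = 0.0315, adjusted p = 0.855 with an estimated correlation), with COL18A1 (-0.66) and COL6A1 (-0.37, with a dimmer probe at -0.11, and not passing on the Cy3 arrays alone). The list call did not hold without siWRN387 replicate 1 (adjusted p = 0.365). With siWRN385, these histone, heat shock and extracellular matrix lists were not called (camera adjusted p = 0.0848, 0.623 and 0.227).

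In the labelled siWRN385 RNA the heme oxygenase HMOX1 (0.62), the complex I subunit NDUFB3 (0.66) and DGCR8, a partner of Drosha in microRNA processing (0.83, with a dimmer probe at 0.02), were higher. DGCR8 read 0.40 with siWRN387. Their lists were not called with siWRN385: the camera adjusted p was 0.962 for oxidative stress, 0.308 for oxidative phosphorylation and 0.557 for small RNA pathway genes. The junction genes OCLN (0.31 and -0.24) and CDH1 (0.26 and -0.19) and the immediate early gene EGR1 (-0.27 and 0.23) had opposite signs with siWRN385 and siWRN387. Marker lists of other cell types did not pass in the average: the camera adjusted p was 0.603 for neuronal, 0.831 for kidney tubule, 0.916 for epithelial, 0.603 for fibroblast and 0.852 for blood cell markers, although neurofilament NEFM (0.49 and 1.01) passed with both siRNAs.

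The arrays carry 10 control probes for adenovirus E1A, meant for spike-in RNA and used in no comparison. For 8 of them the median processed signal over array channels was above 2 times that of the negative control spots. Over all 10 it ranged from 1.03 to 19.3 times. For each of the 8 brighter probes the mean log2 ratio of labelled siWRN over labelled scrambled was below 0, and the lowest was -0.08.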
